A study of Drosophila melanogaster and Drosophila biarmipes with 20 samples.

How the data were processed

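ATAC-seq regions of male D. melanogaster and D. biarmipes wings at 5 stages were analysed from the authors' lists, 1 for each of the 20 libraries, with 10 further lists called on pooled replicates. Per the submitters' processing notes, the tools were Bowtie2, Picard, SAMtools, MACS2 and HOMER, with no versions, and the build was dm6. The build of the D. biarmipes scaffolds is not given in the sources used here. Per the file headers, the lists came from HOMER findPeaks in its histone style, which joins enriched windows into regions of varying width, with no input control. Its window was 100 bp, the Poisson p threshold 0.001, the local filter 10 kb with a p threshold of 0.0001, and the genome size 120 Mb for both species. The same size for both species, and no shift of the transposase cut named in the headers, limit how exactly widths and counts of the species compare.

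The score column of the deposited lists holds the constant 1, so it ranks nothing. The other columns are coordinates, which were written here counted from 1. List order went with region width (Spearman's rho -0.985 to -0.958) and was used in place of the score where a stricter list was wanted. Stricter lists by score or q were not used here. Per the file headers, the fragment length estimated by the caller was 50 to 58 bp in 6 D. melanogaster libraries, 52 to 56 bp in D. biarmipes and 138 to 208 bp in 4 D. melanogaster libraries (replicate 1 at 0%, both replicates at 48% and replicate 2 at 60%). This estimate, made for each library, is called the fragment length setting below. The headers also place the libraries in 2 dated folders, which are taken here as 2 sequencing runs. The first held all replicate 1 libraries and both replicates of 48%, 12 libraries, and the second the 8 others, so 48% has no library in the second run and leaving out replicate 2 gives the values within the first. The labels name 47% in some places for the stage called 48% here.

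Regions were the union of the 10 lists of a species, with overlapping entries merged, which gave 98646 in D. melanogaster and 106112 in D. biarmipes. A library listed a region if any of its own entries shared at least 1 base with it. The gene table used was that of the same D. melanogaster assembly, with 1 span per gene and no strand or exons, so transcription start sites, introns and exons were not used here. The planned distance to a start site was replaced by the distance to the nearer gene end. A region was assigned to the protein-coding gene it overlapped, the one with the nearest end if several, or otherwise to the gene with the nearest end within 10 kb, which assigned 93.2% of D. melanogaster regions. The planned promoter share became the share within 500 bp of either gene end. Gene lists, the comparison of species at genes and the yellow locus were not run for D. biarmipes.

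Before the data were examined, the rule for opened and closed regions, 11 gene lists, the main tests, some of the alternatives and the rule for named genes were fixed. Of the list symbols, 4 had no match. The named genes are y, the 6 genes with most opened and the 6 with most closed regions in each main comparison, and in each list up to 2 genes with most opened and 1 with most closed regions. Genes or regions singled out beyond that were chosen after their values were seen. Lists were tested against 10000 random lists matched on regions per gene, among genes with an assessed region (11104 from 0% to 48% and 11668 from 48% to 78%), with Benjamini-Hochberg adjustment over the lists. Species were compared by exact permutation within stages and relations with stage by 100000 permutations. Where labels say biological replicates but do not say how wings were divided among them, p-values from permuting libraries measure the spread between these libraries. Those of the gene lists measure the spread between genes, and those of Fisher's exact test between regions. Both hold the libraries fixed and leave out the spread between them.

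Alternatives were the first 10000 regions or the first 50% of each list, an equal number per library, strongly listed regions (among the first 20000 of both libraries of one stage and absent from both full lists of the other), coverage of at least 50% of a region, bins of 1 kb, each replicate left out, the authors' pooled lists, autosomal arms alone and Fisher's exact test. Those by list order, the equal number, strongly listed regions and autosomal arms alone were chosen after the data had been examined. Of the 10 pooled lists, 7 had the summed tags of their replicates within 0.01%. The 3 others, of D. biarmipes, held 92.6% at 0%, 60.4% at 60% and 29.6% at 69% of their replicates' tags and were not used.

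The rule and tests were tested on simulated data. For D. melanogaster from 48% to 78%, 4000 changed regions were simulated among 37127 regions at the libraries' own listing rates. The rule recovered 63.7% of the changed regions and called 5.56% of unchanged regions, 1.05% as opened and 4.52% as closed. Simulated libraries never listed a region absent at their stage. The 0 calls in the wrong direction were thus fixed by construction. In the list test for opened regions of that comparison, over 11668 genes, 4.5% of 200 random lists passed an unadjusted threshold of 0.05, and 98.0% of 50 lists did with 20% of their remaining regions set to opened. Tags are not independent molecules, and intervals cover counting error only. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.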

Results

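Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in male wings of Drosophila melanogaster and Drosophila biarmipes. The wings came from 5 stages, named by the share of pupal development completed (0%, 48%, 60%, 69% and 78%). Wing imaginal discs were used at 0% and pupal wings later, and wings older than 60% were cut before disruption. Each of the 10 groups of species and stage held 2 libraries, 20 in all, which the labels call biological replicates. The lists of open regions rested on 56282342 to 119278540 tags per library in D. melanogaster and on 63311975 to 123870286 in D. biarmipes. They held 41485 to 80705 regions in D. melanogaster and 50630 to 68714 in D. biarmipes. With 2 libraries against 2, the smallest exact two-sided p at a single region is 0.333, so single regions carry no p-value. A region was called opened or closed where both libraries of one stage listed it and neither library of the other did. The same count over the 2 crossed divisions, which put 1 library of each stage on each side, is given beside it. Regions that change with stage cannot meet the crossed rule, so this is not the number of false calls.

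The stages had been chosen from the expression of yellow, a secreted protein needed for black pigment, so the regions around its gene were described first. In dm6 the gene y (Dmel_CG3757) spans X from 356509 to 361245, inside the larger annotated gene CG32816, and 14 regions lay in it or within 10 kb of it. At 48% both D. melanogaster libraries listed open chromatin over most of the gene and past its end. Replicate 1 listed a region of 3015 bp from 358889 to 361903, with none between 356673 and 357978, and replicate 2 a single region of 6987 bp from 357760 to 364746, with none between 356917 and 357572. The length of the gene covered by listed regions was measured after these regions had been seen. It was 3730 ± 448 bp of 4737 bp at 48% (SD, n = 2). It was 165 ± 52.3 bp at 0%, 245 ± 7.78 bp at 60%, 237 ± 83.4 bp at 69% and 139 ± 17.7 bp at 78% (SD, n = 2 each). As a share of the gene this was 72.0% and 85.4% in the libraries of 48%, and 2.66% to 6.25% in the 8 other libraries. The 48% libraries had been called with a long fragment length setting, but so had 1 library of 0% and 1 of 60%, which covered 2.70% and 5.05% of the gene.

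Smaller regions around y followed other courses. A region at the start of the gene, from 356175 to 356961, was listed in both libraries at 0%, 48%, 60% and 69% and in neither at 78%. Before the gene, the regions from 350177 to 351427 and from 353586 to 355146 were listed in all 10 libraries, and both were covered furthest at 48%. The region from 352397 to 352940 was listed in both 48% libraries and in 1 other, at 69%. The region from 351639 to 351883 was listed in both libraries at 69% and 78% and in no earlier one. Beyond the gene, a region from 366560 to 367569 and another from 369529 to 370552 were listed in both libraries at 0% and 48% and in none from 60% on. In the second, the regions listed at 0% reached into the proneural gene ac, which spans 370031 to 370947, and those listed at 48% ended before it, at 369880 and 369941. Both libraries listed 9 of the 14 regions at 0%, 7 at 48%, 4 at 60%, 6 at 69% and 4 at 78%. The yellow gene of D. biarmipes was not analysed here.

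**Figure D1:**
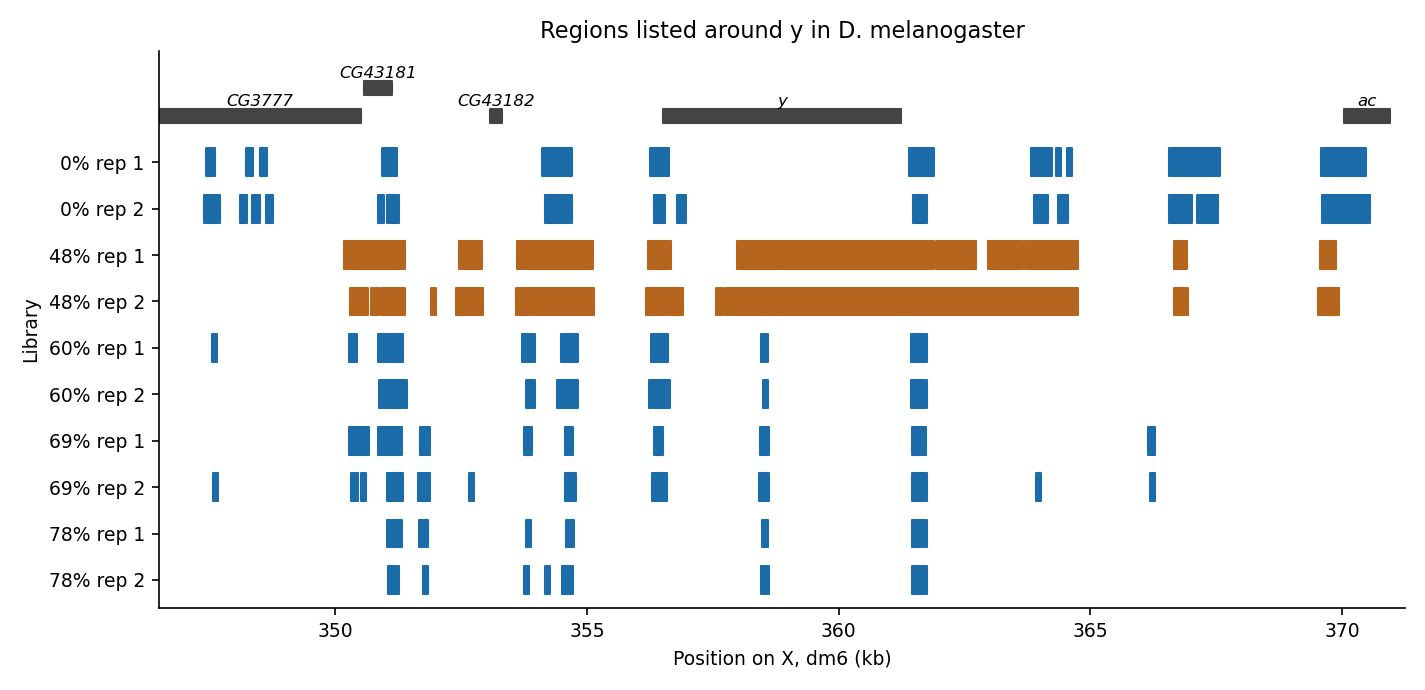
Listed regions (bars) in each of the 10 D. melanogaster libraries along X in kb (dm6), from 10 kb before y to 10 kb after it, with 48% in brown and the other stages in blue; genes are dark bars above, without CG32816, which spans the whole window. At 48% regions covered 72.0% and 85.4% of y, against 2.66% to 6.25% in the other 8 libraries.

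Libraries of one stage resembled each other more than libraries of different stages. In D. melanogaster the Jaccard index, the shared over the combined covered length, was 0.688 ± 0.0715 within stages (SD, n = 5 pairs) and 0.471 ± 0.109 between stages (SD, n = 40 pairs). The difference of 0.217 was the largest over all pairings of the 10 libraries (one-sided exact permutation test, p = 0.00106, the smallest these pairings can give). In D. biarmipes the index was 0.739 ± 0.0321 within stages (SD, n = 5 pairs) and 0.496 ± 0.106 between stages (SD, n = 40 pairs), with a difference of 0.244 and the same exact p of 0.00106. The nearest library was of the same stage for 8 of the 10 D. melanogaster libraries and for 10 of the 10 D. biarmipes libraries.

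From the disc at 0% to the wing at 48%, more D. melanogaster regions closed than opened in the full lists. The most opened regions lay in mtgo (20 of its 83, with 14 closed), in the transcription factor gene mamo (17 of 56, with 13 closed) and in the ecdysone-induced ETS factor gene Eip74EF (16 of 47, with 1 closed). Next came tai, which encodes a coactivator of the ecdysone receptor (15 of 58, with 10 closed), the RNA-binding protein gene sm (15 of 92, with 0 closed) and the adhesion molecule gene kirre (14 of 105, with more closed, 26). The most closed regions lay in the RNA-binding protein gene bru3 (59 of its 211, with 3 opened), the adhesion gene Con (45 of 133), heph (43 of 138, with 5 opened), CG34354 (42 of 117), Gfrl (39 of 108) and olf413 (38 of 101, with 1 opened). Of 66579 regions listed in at least 1 of the 4 libraries, 5887 opened (8.84%) and 13204 closed (19.8%), against 24 to 783 in the crossed divisions. They lay in or near 3163 genes with an opened region and 4071 with a closed one. Both 48% lists were short, and the excess of closed regions was not seen with an equal number of regions per library (7896 opened and 7813 closed) or in the first 10000 of each list (2815 and 2613). Lists of equal length bring the opened and closed counts near each other by construction, so these values do not test the direction.

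Members of the fixed gene lists moved in both directions between 0% and 48%. Among ecdysone response genes, Eip75B opened at 8 and closed at 6 of 51 regions, and br, an early ecdysone-induced transcription factor gene, opened at 2 and closed at 23 of 53. Among wing patterning genes, ab opened at 8 and closed at 2 of 24 regions, nub, a wing POU factor gene, opened at 5 and closed at 2 of 26, and the homeobox gene hth opened at 3 and closed at 26 of 89. For the apical matrix and planar polarity, dpy, which encodes a giant apical matrix protein, opened at 12 and closed at 26 of 120 regions, and the atypical cadherin gene stan opened at 10 and closed at 4 of 32. Cuticle and chitin genes included the chitinase gene Cht6 (4 of 16 opened and 2 closed), Cpr66Cb (3 of 5 opened) and TwdlQ (7 of 13 closed). In the pigmentation list, stw and yellow-e each opened at 3 of 8 regions, and the tyrosine hydroxylase gene ple opened at 1 and closed at 3 of 9. None of the 3 regions assigned to y met the rule: 2 were listed in both libraries of each stage, and the third, from 357572 to 357723, in 1 library of 48% and none of 0%.

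Of the 11 lists, 1 differed from matched random lists in its opened regions from 0% to 48% (two-sided permutation test on 10000 lists, Benjamini-Hochberg over the lists). Ribosomal protein genes had 6 of 165 regions opened (3.64%), against a median of 10.6% in random lists (adjusted permutation p = 0.0286). RpL23 and RpL24 each opened at 1 of 2 regions and RpL3 closed at 2 of 3. On the autosomal arms 2 and 3 alone the share was 4.2% against 10.3% (adjusted permutation p = 0.143), and without replicate 2 it was 13.4% against 20.9% (0.219). The adjusted p ranged from 0.0066 to 0.614 over the alternatives. The other opened shares were 12.6% for the apical matrix list and 11.8% for ecdysone response (adjusted permutation p = 0.306 each), 8.25% for cuticle and chitin (0.394), 9.54% for wing patterning and 5.62% for muscle markers (0.609 each). They were 11.8% for pigmentation, 11.5% for cell cycle, 7.01% for sensory organ and neuron markers and 9.55% for trachea markers (0.747 each) and 7.93% for hemocyte markers (0.883). No list passed for closed regions; at an unadjusted p under 0.05 there was 1, muscle markers, with 95 of 320 regions closed (29.7%) against a median of 21.3% (adjusted permutation p = 0.178). Of the 95, 26 lay in bt on chromosome 4, and on the autosomal arms 2 and 3 alone the muscle share was 25.5% against 21.1% (adjusted permutation p = 0.581). For closed regions Fisher's exact test over regions passed muscle markers, above the other regions, and ribosomal protein genes, below them. Wing patterning closed less often than random lists without replicate 1 (adjusted permutation p = 0.0484) and more often among strongly listed regions (0.0022).

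Other tissues' markers among the named genes of this comparison were bt, a giant muscle protein gene on chromosome 4 (26 of 45 regions closed), the muscle and nuclear anchor gene Msp300 (4 of 65 opened and 14 closed) and twi (3 of 19 opened and 2 closed). Sensory organ and neuron markers were cpo (6 of 52 opened and 7 closed), pros (5 of 33 opened and 5 closed) and scrt (9 of 20 closed). Hemocyte markers were lz (3 of 9 opened and 1 closed) and ush (3 of 43 opened and 12 closed). On the trachea list were sano (8 of 73 opened and 18 closed) and the FGF ligand gene bnl (5 of 43 opened and 7 closed). As the gene of a secreted ligand, bnl need not mark tracheal cells themselves. Cell cycle genes were E2f1 (3 of 29 opened and 5 closed) and CycA (2 of 5 opened).

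**Figure D2:**
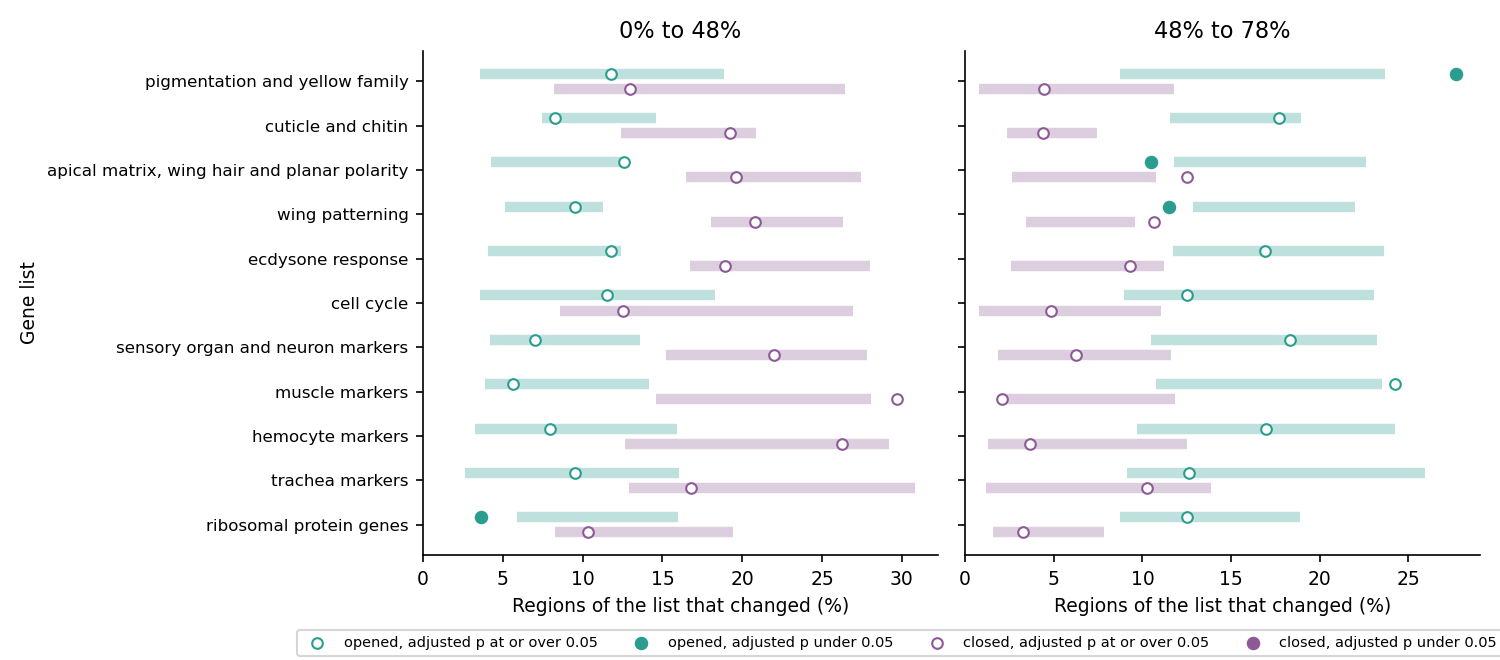
Share of each list's assessed regions (x axis, %) that opened (green) or closed (purple) in D. melanogaster, with pale bars for the middle 95% of 10000 matched random lists; filled points have an adjusted p under 0.05. The filled points are the opened share of ribosomal protein genes from 0% to 48% (3.64%) and, from 48% to 78%, those of pigmentation (27.7%), apical matrix (10.5%) and wing patterning genes (11.5%).

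From 48% to 78%, regions of the pigmentation and yellow family list opened more often than those of random lists in D. melanogaster, when both replicates entered. Ddc, the dopa decarboxylase gene of the melanin and sclerotin pathway, opened at 5 of 7 regions, and the laccase-like gene stw opened at 6 and closed at 1 of 17, while y closed at 1 of 3 and speck at 2 of 8. Of the 112 regions of the list, 31 opened (27.7%), in 14 of 25 genes, against a median of 15.6% in random lists (adjusted p = 0.0418, two-sided permutation test). The call was lost without replicate 1 (49.0% against 44.6%, adjusted permutation p = 0.583) and without replicate 2 (43.3% against 42.2%, 0.882). Among cuticle genes the chitin-binding protein gene Gasp, also on the trachea list, opened at 5 of 12 regions, and among ecdysone response genes the late factor genes Eip93F and ftz-f1 opened at 21 of 57 (with 4 closed) and 13 of 38. Cpr, on the cuticle list by its name, encodes cytochrome P450 reductase and opened at 6 of 12 regions.

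Over all genes, the most opened regions from 48% to 78% lay in DIP-lambda (110 of its 224, with 1 closed), CG17839 (43 of 97), bru3 (29 of 166, with 1 closed), the sex determination and behaviour gene fru (27 of 115, with 12 closed), Msp300 (26 of 84) and the MAP kinase gene rl (25 of 56). DIP-lambda and rl lie on 2R at 326768 to 705848 and 1071462 to 1125927, next to the centromere. The most closed regions lay in the splicing factor gene mbl (33 of 119, with 4 opened), kirre (21 of 56, with 6 opened), sm (20 of 91, with 2 opened), f, which encodes an actin-bundling protein of bristles and hairs (15 of 33), CG31176 (14 of 45) and bbg (14 of 70, with 8 opened). Of 71157 assessed regions, 11773 opened (16.5%) and 3746 closed (5.26%), against 159 to 1151 in the crossed divisions. In the simulation, in which each library missed regions independently at its own rate, 1.05% of unchanged regions were called opened and 4.52% closed. Simulated regions were all drawn from those listed in at least 1 library of 48%, while the assessed regions include those listed at 78% alone. The simulated and observed closed shares thus have unlike bases and do not compare directly. Of the regions listed in both 48% libraries, 13.5% closed. With an equal number of regions taken from each library 4859 opened and 6122 closed, and in the first 10000 of each list 1808 and 2443, which, as lists of equal length, do not test the direction. Both 48% libraries had been called with a longer fragment length setting and listed 46454 ± 7027 regions (SD, n = 2), fewer than the 74641 ± 8572 at 78% (SD, n = 2).

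The apical matrix and wing patterning lists opened less often than random lists from 48% to 78%. Regions opened were 58 of 552 in the apical matrix list (10.5% against a median of 16.4%) and 81 of 706 in the wing patterning list (11.5% against 16.5%), each with an adjusted p of 0.0418 (two-sided permutation test). Their named members were dpy (9 of 108 opened and 7 closed), the planar polarity gene pk (8 of 35 opened and 4 closed), the zinc finger gene salm (8 of 21 opened and 1 closed), the EGF receptor ligand gene vn (7 of 32 opened and 4 closed) and the T-box gene bi (11 of 26 closed). On the autosomal arms 2 and 3 alone the shares were 11.3% against 16.8% for the apical matrix, 12.4% against 16.9% for wing patterning and 27.0% against 16.1% for pigmentation, but the adjusted permutation p was 0.114 for each. The wing patterning share turned above random among strongly listed regions. Over the alternatives the adjusted p ranged from 0.00443 to 0.882 for pigmentation, from 0.00233 to 0.721 for the apical matrix and from 0.0033 to 0.98 for wing patterning.

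The other lists did not pass for opened regions from 48% to 78% with both replicates. Muscle markers had 82 of 338 regions opened (24.3% against 16.2%, adjusted permutation p = 0.104), among them Msp300 and 9 of 37 regions of sls, a titin-like gene. They passed by Fisher's exact test (adjusted exact p = 0.000737) and without replicate 1 (adjusted permutation p = 0.0471). Sensory organ and neuron markers had 18.3% opened (adjusted permutation p = 0.668), with the synaptic gene brp at 11 of 32 (with 1 closed) and the GABA receptor gene Rdl at 10 of 29. The shares were 17.7% for cuticle and chitin (0.411), 16.9% for ecdysone response and 17.0% for hemocyte markers (0.858 each), 12.5% for cell cycle and 12.6% for trachea markers (0.635 each), and 12.5% for ribosomal protein genes (0.828). With single replicates, ribosomal protein genes opened less often than random lists without replicate 1 and without replicate 2 (adjusted permutation p = 0.0132 and 0.0456), ecdysone response without replicate 1 (0.0471) and trachea markers without replicate 2 (0.0301). No list passed for closed regions; at an unadjusted p under 0.05 there were 3, the apical matrix list (69 of 552, 12.5% against 5.87%), wing patterning (75 of 706, 10.6% against 6.06%), each with an adjusted permutation p of 0.0869, and muscle markers (7 of 338, 2.07% against 5.7%, adjusted permutation p = 0.18). Fisher's exact test over regions passed 5 lists for closed regions, and the apical matrix list passed without replicate 2 (adjusted permutation p = 0.0044). Random lists were not matched on chromosome, and X regions closed more often over this comparison, as given below. On the X lie 6 of the 28 apical matrix genes, 7 of the 42 wing patterning genes and 2 of the 25 muscle markers.

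Further named genes of this comparison were Cht6 (1 of 14 opened and 4 closed), Hr4 (3 of 28 opened and 7 closed), E2f1 (4 of 29 opened and 2 closed), CycG (3 of 14 opened and 1 closed) and fzr (3 of 7 closed). They also included futsch (4 of 6 closed), wupA, which encodes troponin I (2 of 2 closed), the scavenger receptor gene Sr-CI (5 of 11 opened), ush (7 of 44 opened and 1 closed), lz (3 of 7 closed) and sano (8 of 62 opened and 8 closed). RpL3 and RpL35A each opened at 2 of 4 regions and RpL23 closed at 1 of 2.

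Step by step after 48%, the full lists of D. melanogaster held more opened than closed regions until 69%. From 48% to 60%, 6043 regions opened and 2169 closed, from 60% to 69%, 4758 and 1661, and from 69% to 78%, 2353 and 3228. The highest counts of the crossed divisions were 1363, 1483 and 1966. The last step turned without replicate 1, with 15739 opened and 9430 closed. The counts also went with the fragment length setting. From replicate 1 of 48%, 18984 opened and 4058 closed to the short-setting library of 60%, and 10713 and 5006 to the long-setting one. To replicate 1 of 69%, 16584 opened and 4040 closed from the long-setting library of 60%, and 10883 and 7558 from the short-setting one. The setting and the stage were not separated here, nor was the cutting of wings older than 60%. In the first 10000 of each list, 1090 opened and 1363 closed, then 809 and 835, then 504 and 680, from lists of equal length. Of 98646 regions in the union of the 10 libraries, 16507 were listed in all 10. Both libraries of a single stage and no other library listed 5763 regions at 0%, 917 at 48%, 297 at 60%, 701 at 69% and 1514 at 78%.

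**Figure D3:**
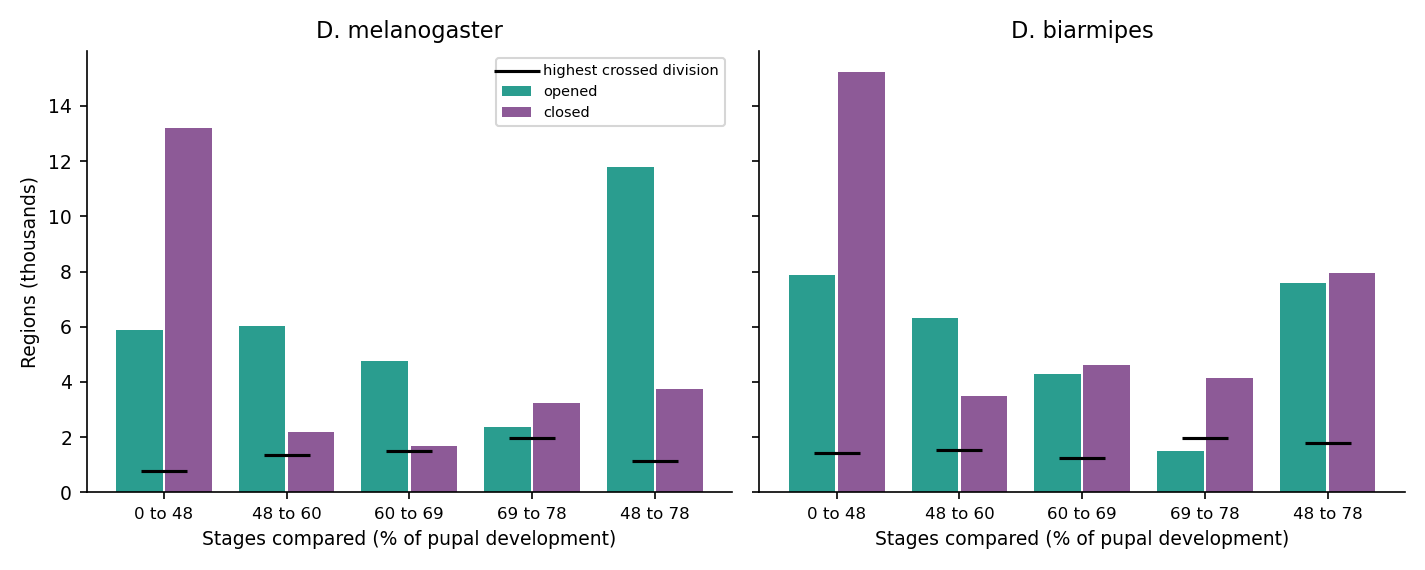
Regions (y axis, in units of 1000) that opened (green) or closed (purple) between pairs of stages in each species; black lines give the highest count of the crossed divisions of the same 4 libraries. From 48% to 78%, 11773 regions opened and 3746 closed in D. melanogaster, and 7601 opened and 7949 closed in D. biarmipes.

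Regions on the X closed more often than regions on the autosomes after 48%, as counted after the data had been examined. From 48% to 78%, 1155 of 3591 X regions closed (32.2%, Wilson 95% interval 30.7% to 33.7%), against 2566 of 23874 on the arms of chromosomes 2 and 3 (10.7%, 10.4% to 11.1%). The 4 autosomal arms lay between 10.7% and 10.9%, and chromosome 4 at 12.2% (8.21% to 17.8%). The X share was above that of arms 2 and 3 from 48% to 60% (15.5% and 6.69%), from 60% to 69% (10.1% and 4.29%) and from 69% to 78% (13.9% and 7.44%), but not from 0% to 48% (32.3% and 36.6%). Between single libraries of 48% and 78%, X regions closed at up to 40.4% and those on arms 2 and 3 at 16.5% to 25.1%, a ratio of 1.61 to 2.43 against 2.99 with both replicates. The intervals treat regions as independent, cover counting error only and leave out this spread between libraries. The share of tags in listed regions fell over the same steps after 48%, as given below, and was not separated from the closing of X regions. Among the genes named above, y, mamo, br, kirre, f, bi, Cht6, Hr4, fzr, futsch, wupA and lz lie on the X.

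**Figure D4:**
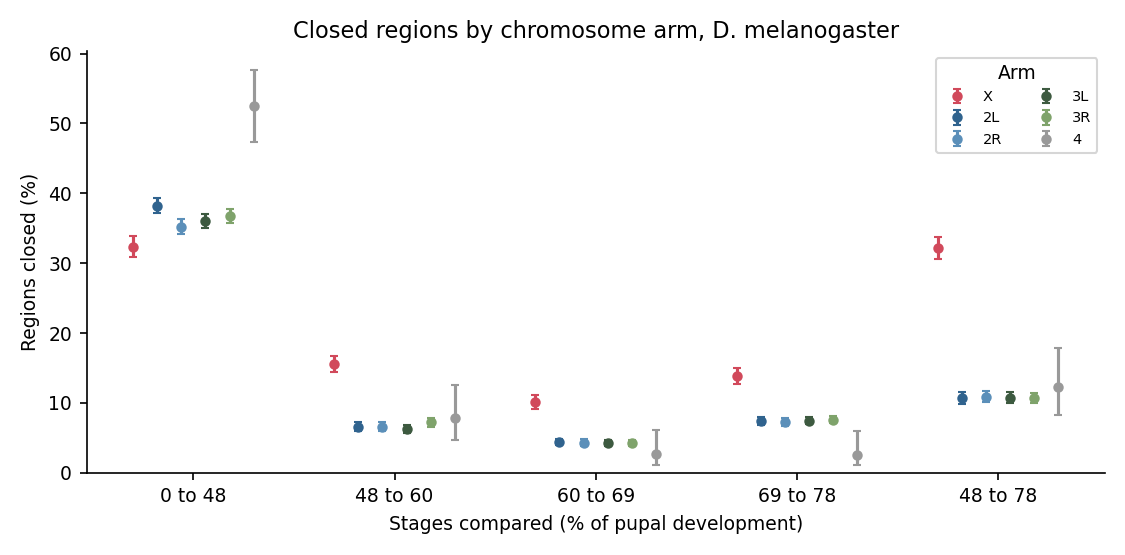
Share of the regions listed in both libraries of the earlier stage that closed (y axis, %), by chromosome arm and pair of stages in D. melanogaster; error bars are Wilson 95% intervals. From 48% to 78% the X stood at 32.2% and the arms of chromosomes 2 and 3 at 10.7% to 10.9%.

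In D. biarmipes, whose regions lie on unplaced scaffolds and were not tied to genes here, closing also exceeded opening from 0% to 48%. Of 82603 assessed regions, 7863 opened (9.52%) and 15237 closed (18.4%), against 218 to 1422 in the crossed divisions. From 48% to 78%, 7601 of 73382 opened (10.4%) and 7949 closed (10.8%), against 122 to 1785. By step, 6321 opened and 3485 closed from 48% to 60%, 4282 and 4629 from 60% to 69%, and 1507 and 4136 from 69% to 78%, with crossed divisions of up to 1526, 1231 and 1974. The 1507 opened from 69% to 78% were thus fewer than the highest crossed count. With single replicates the direction turned from 69% to 78% without replicate 1 (10352 opened and 9368 closed), from 60% to 69% without replicate 2 (11121 and 10972), and from 48% to 78% without replicate 1 (18358 and 17818) and without replicate 2 (14961 and 12340). Of 106112 regions, 19794 were listed in all 10 libraries, and 9773 at 0%, 1629 at 48%, 816 at 60%, 642 at 69% and 927 at 78% in both libraries of that stage and no other.

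The species differed in the length of genome covered. Listed regions covered 20.6 ± 1.92 Mb in D. melanogaster and 16.9 ± 1.67 Mb in D. biarmipes (SD, n = 10 each), a difference of 3.78 Mb (exact two-sided permutation test within stages, p = 0.000257, the smallest these arrangements can give, adjusted p = 0.000772 over 3 measures). The number of regions was 65092 ± 13942 and 59739 ± 5092 (SD, n = 10 each, adjusted p = 0.316), and the median width 204 ± 56.1 bp and 188 ± 6.72 bp (SD, n = 10 each, adjusted p = 0.491, exact permutation tests). Without the 4 D. melanogaster libraries called with a long setting, the difference in number rose to 15113 regions (adjusted exact p = 0.00463) and that in width turned to -8.53 bp (adjusted exact p = 0.037). This took out both D. melanogaster libraries of 48%, while the D. biarmipes mean of 59739 regions still included those of 48%. The stages compared were thus not the same in both species, and these values do not separate the setting from the stage. The genomes, and so the lengths that could be covered, were not the same.

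**Figure D5:**
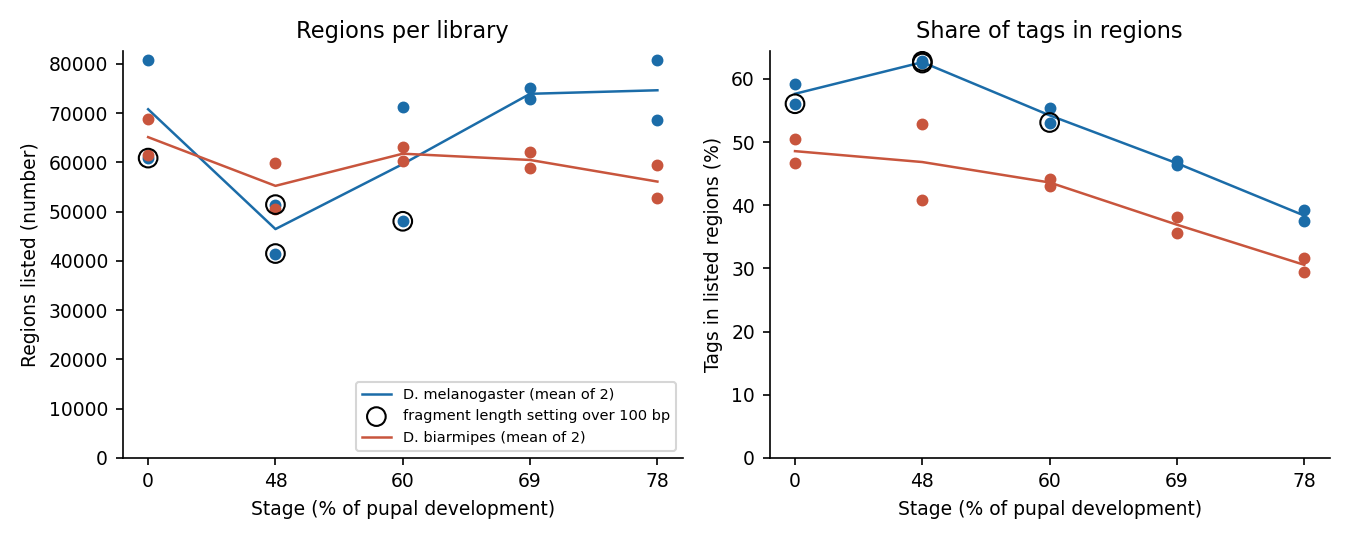
Number of listed regions (left) and percent of tags in them (right) by stage; points are libraries, lines join the means of 2 and rings mark the 4 D. melanogaster libraries with a fragment length setting over 100 bp. The ringed libraries held 41485 to 60866 regions and the other 6 of the species 68580 to 80705.

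The mean share of tags in open regions fell from stage to stage after 48% in both species. In D. melanogaster it was 57.6 ± 2.23% at 0%, 62.6 ± 0.197% at 48%, 54.2 ± 1.6% at 60%, 46.6 ± 0.431% at 69% and 38.4 ± 1.23% at 78% (SD, n = 2 each). In D. biarmipes it was 48.6 ± 2.76%, 46.8 ± 8.5%, 43.6 ± 0.873%, 36.9 ± 1.8% and 30.6 ± 1.63% (SD, n = 2 each). It was thus highest at 48% in D. melanogaster, and in D. biarmipes the 48% libraries, at 40.8% and 52.8%, lay on either side of those at 0% and at 60%. Of 6 relations computed as a family, those of this share and of the X share were added after the data had been examined. Spearman's rho of the share with stage was -0.886 in each species (permutation p = 0.00165 and 0.00163, adjusted p = 0.0033 each), while Pearson's r was -0.65 and -0.736 and did not pass (permutation p = 0.0402 and 0.015, adjusted p = 0.121 and 0.0902). Without the 2 libraries at 0%, r was -0.995 (adjusted permutation p = 0.00138) and -0.873 (0.00858). Within the sequencing run that held 6 libraries of each species, rho was -0.812 in each species (permutation p = 0.0717 and 0.072) and r was -0.541 (permutation p = 0.267) and -0.591 (0.215). The other run held 4 libraries per species, under the minimum of 6 used here for a correlation.

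The number of regions had no detected relation with stage. Pearson's r was 0.0737 in D. melanogaster (rho 0.271, permutation p = 0.849 and 0.461) and -0.496 in D. biarmipes (rho -0.419, permutation p = 0.139 and 0.239). Without the 2 libraries at 0%, r was 0.824 (adjusted permutation p = 0.0202) and 0.0846 (0.839), and without the 4 libraries with a long setting it was -0.506 in D. melanogaster (0.366). The share of D. melanogaster regions within 500 bp of a gene end was 30.6 ± 1.15% at 0%, 34.7 ± 0.853% at 48%, 31.9 ± 0.764% at 60%, 31.0 ± 0.0671% at 69% and 30.9 ± 2.04% at 78% (SD, n = 2 each). Its r with stage was 0.0614 (rho -0.295, permutation p = 0.875 and 0.42) and -0.813 without the 0% libraries (adjusted permutation p = 0.0202). Within the run of 6 libraries, r was 0.354 and -0.251 for the number of regions (permutation p = 0.509 and 0.673), with rho of 0.638 and 0.087 (0.193 and 0.866). For the share near gene ends r was 0.053 and rho -0.29 (permutation p = 0.922 and 0.597). The X share of regions on the arms was 9.65 ± 0.172% at 0%, 11.2 ± 0.902% at 48%, 9.11 ± 0.163% at 60%, 7.81 ± 0.216% at 69% and 6.41 ± 0.626% at 78% (SD, n = 2 each). Its rho with stage was -0.886 (adjusted permutation p = 0.0033), with r of -0.565 (0.186), -0.975 without the 0% libraries (0.00138) and within the run of 6 libraries rho was -0.812 (permutation p = 0.072) and r -0.469 (0.358).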

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

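The stricter lists by list order, the equal number, strongly listed regions, autosomal arms alone and the sets without long-setting libraries were chosen after seeing the data; the cause of the differences below was not tested unless fewer regions or libraries entered by construction. Replicate concordance kept its direction and its side of the threshold under every alternative run (difference 0.168 to 0.299 in D. melanogaster and 0.17 to 0.34 in D. biarmipes, exact permutation p 0.00106 to 0.00952). Replicate numbers did not pair the samples (correlations -0.0553 to 0.0232 and -0.0262 to 0.0225). With the replicate block the concordance differences were 0.217 and 0.244 (exact p = 0.00833 each), the covered length differed by 3.78 Mb (exact adjusted p = 0.00586), and the block changed no other call; region counts under it, and so the gene lists tested on them, are identical by construction.

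In the first 10000 regions of each list, opened and closed were 2815 and 2613 (0% to 48%), 1090 and 1363 (48% to 60%), 809 and 835 (60% to 69%), 504 and 680 (69% to 78%) and 1808 and 2443 (48% to 78%) in D. melanogaster, and 3261 and 3408, 1458 and 1548, 1302 and 1421, 591 and 749, and 2406 and 2734 in D. biarmipes. In the first 50% of each list they were 3719 and 8794 from 0% to 48% with 6865 and 2682 from 48% to 78%, and in D. biarmipes 4842 and 8671, then 4808 and 4987. With strongly listed regions they were 1835 and 2146, then 1089 and 1112, and in D. biarmipes 1852 and 2372, then 850 and 1765. With an equal number per library, 7896 opened and 7813 closed from 0% to 48% in D. melanogaster, then 4859 and 6122; lists of equal length bring both counts together by construction. In the authors' pooled lists they were 9064 and 28907, then 31243 and 6445, and in D. biarmipes 18250 and 15379 from 48% to 78%. With at least 50% of a region covered, 6857 closed from 48% to 78% in D. melanogaster.

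With single replicates, D. melanogaster counts ranged from 9142 to 10056 opened and 18217 to 28203 closed (0% to 48%), 8593 to 18984 and 4058 to 6665 (48% to 60%), 10883 to 16103 and 3882 to 7558 (60% to 69%), 9612 to 15739 and 9430 to 12926 (69% to 78%), and 22434 to 27667 and 7209 to 7497 (48% to 78%). In D. biarmipes they ranged from 12999 to 16276 and 23337 to 26475, 12533 to 18639 and 6184 to 11818, 10071 to 11121 and 10972 to 11230, 5312 to 10352 and 9368 to 15295, and 14961 to 18358 and 12340 to 17818. The difference in covered length was then 3.61 to 3.95 Mb and could not pass, since the 32 arrangements left give an exact p of 0.0625 at least.

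Of the gene lists, 1 passed for opened and 0 for closed from 0% to 48%, and 3 and 0 from 48% to 78%. By Fisher's exact test 0 and 2 lists passed for opened and closed from 0% to 48%, and 4 and 5 from 48% to 78%. On autosomal arms alone, and in the first 10000 regions, 0 passed for opened in each comparison. Within 1 kb of a gene end 0 and 1 passed for opened, with 50% coverage 1 for opened and 1 for closed from 0% to 48% and 1 for opened from 48% to 78%, and with strongly listed regions 0 and 0 for opened and 1 for closed from 0% to 48%. Wing patterning then had 1.7% opened, above random lists. With single replicates 0 to 1 passed for opened and 0 to 1 for closed from 0% to 48%, and 4 to 5 and 0 to 1 from 48% to 78%.

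Around y, both libraries listed 2, 3, 0, 0 and 0 regions from 0% to 78% within the first 10000, covering 0, 3208.5, 0, 0 and 0 bp of the gene. The pooled lists covered 222 bp at 0% and 311 bp at 60%. Without the 0% libraries r with stage was 0.824 and 0.0846 for the number of regions, -0.813 for the share near gene ends, -0.995 and -0.873 for tags in regions and -0.975 for the X share, which was -0.841 in the first 10000. Without the long-setting libraries the number of regions differed by 15113.2 and the width by -8.53 bp between species. D. biarmipes then still held its 48% libraries and D. melanogaster held none of that stage. Without the same libraries, r for the number in D. melanogaster was -0.506. Over the alternatives of the genes and called lists named in the report, 175 moved a gene's count by over 1.5 times, 20 ended a list's call, 1 turned it and 334 did none of these. Of those of the results that answer a comparison, 113 moved the value, 4 turned it, 2 ended a call, 6 added one and 94 did none of these. Planned settings on score or q, the pooled list of D. biarmipes at 0% and the comparison of species at genes were not run, and the relations with stage were not run without 1 replicate, which leaves 5 libraries, under the minimum of 6 used here.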

Other observations

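All tests of this part were chosen, or their limits last worded, after the data had been examined, and the rule for covered genes was made after y had been seen. Few genes shared the course of y. Of 7406 D. melanogaster genes of at least 2 kb, y ranked 22 in the share of its length covered at 48% (78.7 ± 9.46%, SD, n = 2), above 99.7% of the genes, and 6421 at 0%. Its lower 48% library stood 65.8 points above its highest other library, rank 2 of 7406. Covered over at least 50% in both libraries of 1 stage and at most 20% in all 8 others were 3 genes at 48% (y, CG12003 at 83.6 ± 19.5% and CG44085 at 56.8 ± 5.46%), 6 at 0%, 1 at 78% and none at 60% or 69%. The gene at 78%, CG14961, was covered over its whole length of 3119 bp in both libraries and over at most 0.321% in the others. Those at 0% were Hsp68, a heat shock protein gene covered over its whole length, Mal-A2, CG31371, CG31933, CG17781 and CG6209. No pair of libraries of different stages gave any gene by this rule (40 pairs).

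The broad coverage of y at 48% was weighed against the fragment length setting. The 2 other D. melanogaster libraries called with a long setting covered at most 5.05% of the gene, which argues against that setting as the cause. The stage remains open as an untested biological explanation. DNA from a construct that carries y was not tested.

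The excess of closing X regions after 48% was weighed against weak signal and sample sex. Within 20 strata of list position at 48%, the odds of closing on the X were 4.55 times those on the arms of chromosomes 2 and 3 (95% interval 4.16 to 4.97). They were higher in 20 of the 20 strata, which argues against a lower list position of X regions as the cause. List position went with region width, and the lists hold no tag counts per region. X regions lying nearer the calling limit thus stay open. The mean share of tags in regions also fell, from 62.6% at 48% to 38.4% at 78%. Whether this fall acted more on X regions than on autosomal ones was not tested. The test for sample sex replaced an earlier one on Y regions, dropped after its result was seen, which decides nothing because its direction depends on the sequences called Y. With unplaced Y sequences Y regions were 1.46 ± 0.198 times the unplaced ones at 48% and 0.985 ± 0.0403 times at 78%, but those of the assembled Y alone were 0.265 ± 0.0281 and 0.326 ± 0.0188 times all others off the arms (SD, n = 2 each). From 69% to 78%, a step without the 48% libraries, X regions closed 1.86 times as often, which argues against females among the 48% libraries as the whole cause; a mixture that changes over all stages stays open, as does a change in X chromatin with stage, untested here.

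Regions on the Y and unplaced sequences of D. melanogaster, which entered the counts between stages but not the comparison of arms, numbered 215 ± 7.78 at 0%, 149 ± 38.2 at 48%, 366 ± 72.1 at 60%, 590 ± 60.8 at 69% and 750 ± 26.9 at 78% (SD, n = 2 each). In D. biarmipes, where the chromosome of each scaffold was not known here, 6 of the 34 scaffolds with at least 150 regions in both 48% libraries closed at 35.7% to 40.4% of them, and the 28 others at 12.8% to 28.0%.

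The excess of opened over closed regions from 48% to 78% in D. melanogaster was weighed against depth and the fragment length setting. Between the replicate 1 libraries, of which the 78% library had fewer tags (56282342 against 71365625), opened regions were 2.99 times the closed ones, which argues against deeper sequencing at 78%. Among strongly listed regions the ratio was 0.979 (1089 opened and 1112 closed), against 3.14 over all regions, but the same rule lowered it from 0.956 to 0.482 in D. biarmipes, called with short settings throughout, so this test decides nothing. The setting and a change with stage cannot be told apart, because no 48% library was called with a short setting.

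Regions near centromeres opened more often from 48% to 78% on 3 of 4 arms. In the proximal 3 Mb, the share of regions listed in both 78% libraries that had opened was 67.0% on 2R, 62.5% on 3L and 88.2% on 3R, against 31.2%, 33.0% and 30.9% on the rest of each arm, while on 2L it was 30.4% against 31.9%. The shares on 3L and 3R rest on 96 and 51 proximal regions. The share on 2R rests on 509, of which 110 opened in DIP-lambda and 25 in rl, genes already named for their many opened regions. Neither this share nor the odds ratios below were computed without these genes. The odds ratio over the 4 arms was 2.15 (95% interval 1.92 to 2.41), and 2.62 (2.32 to 2.96) with replicate 1 of 60%, called with a short setting, in place of both 48% libraries. These ratios combine arms that differ, and their intervals treat neighbouring regions as independent.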
